A study of Solanum lycopersicum with 12 samples.

How the data were processed

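RNA was extracted with Trizol from flash-frozen tomato pericarp, per the labels' protocols, and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name fastp 0.23.1, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5, without giving each a role. The authors deposited 1 table of read counts per gene, not normalized, and 1 table of FPKM values, each with a column for every library. Gene coordinates in the deposited tables are on the SL4.0 build. The strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes on opposite strands, or of near-identical family members, may therefore be split between them, and values of such genes are uncertain.

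The tables held 35882 features, of which 34688 had a Solyc identifier and 1194 did not, and 10346 had no count in any library. Counts were filtered with edgeR's filterByExpr (min.count 10, min.total.count 15), which left 19664 genes holding 99.949% of the counts. Libraries were scaled by the trimmed mean of M-values (TMM). Each gene was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with 1 coefficient for each of the 4 groups over all 12 libraries, and p-values were adjusted by Benjamini-Hochberg within each of 5 comparisons. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.155 and the prior degrees of freedom were 4.96. Standard errors are the log2 fold change divided by the root of the test's F value. CPM values are TMM-scaled, and intervals and floors (3 counts over a group) cover counting error only.

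Total counts per library ran from 17703054 to 19426192, and the 10 most abundant genes held 4.06 to 7.84% of them. Pearson correlations of log2 CPM between replicates were 0.977 to 0.986. The chi-square per degree of freedom between 2 libraries of a group was 9.86 to 37.5, so no pair differed only by sampling noise. The code was tested on simulated counts with known changes, drawn independently for each gene with a spread set by its abundance alone. It recovered 79, 78, 82, 78 and 54% of genes changed by 1 on the log2 scale and 99, 99, 96, 97 and 93% of those changed by 2, for cr against WT at mature green and at breaker, the stage change in WT and in cr, and the interaction. False calls made up 4.8, 3.3, 3.3, 5.9 and 5.8% of calls. These shares hold for such simulated data and do not cover genes that vary together.

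Before the data were examined, 28 gene lists were fixed, 11 by member and 17 by a pattern in the deposited descriptions. Of 123 members written down, 112 were kept, 9 are not analysed here and 2 had a description other than the pattern written down for them. The lists covered ethylene synthesis and signalling, ethylene response factors, ripening regulators, softening, pectin enzymes, expansins and xyloglucan endotransglucosylases, carotenoid and flavonoid synthesis, aroma volatiles, sugar, starch and acid metabolism, cuticle and steroidal glycoalkaloids. They also covered chlorophyll synthesis and breakdown, photosystems and antennae, core histones, cytosolic ribosomal proteins, heat shock, defence and proteinase inhibitor proteins, aquaporins, auxin-responsive genes, and MADS-box, NAC and WRKY factors. Genes of seed storage and late embryogenesis, and of xylem and lignin, stood for other tissues. Patterns take in some genes of other function, such as lipid-transfer proteins in the proteinase inhibitor and seed lists. Lists were tested with camera in limma 3.58.1 on voom values with a correlation of 0.01, adjusted over 140 tests, and again with an estimated correlation, with which every camera call was lost. The planned test fry asks whether a list changed, without setting it against other genes. At mature green, camera calls without a fry adjusted p under 0.05 were photosystem (0.111), heat shock (0.184), flavonoid (0.136) and ethylene synthesis genes (0.143). Proteinase inhibitor (0.163) and core histone genes (0.0522) were others at that stage. At breaker they were flavonoid (0.109) and ribosomal protein genes (0.495). Over ripening they were ribosomal protein genes in WT (0.0529) and cr (0.143) and heat shock genes in cr (0.122). In the interaction they were photosystem genes (0.147). Heat shock genes (0.0127) and core histones (0.00574) in the interaction passed in fry. So did glycoalkaloid genes at breaker (0.00201), which camera did not call. In simulated data 3 of 3 shifted lists were called. The simulated genes varied independently, so this does not test the preset correlation.

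Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes ripening genes fixed by name, the 5 called genes of largest change each way with a mean of at least 3 log2 CPM and no overlap between the groups, and up to 3 called members of each list. The overlap condition does not apply to the interaction. As run, it also took the most abundant member of each list, called or not. Of all these genes, the fixed ones and the 22 other called genes of smallest adjusted p were kept for each comparison, leaving out features without a Solyc identifier. The largest adjusted p of the 22 was 0.0133, 7.31e-05, 3.57e-07, 3.44e-05 and 0.000677 in the order above. The number kept was set after values of named genes had been seen. RIN, which the rule also names, is not analysed here. Because the genes kept have the smallest adjusted p, they do not stand for the rest of the rule's genes under the alternatives. The mutated gene is named by no label, so no targeted gene was examined.

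Alternatives fixed beforehand were DESeq2 size factors, upper quartile factors, the Wald test of DESeq2 1.42.0, limma's trend test on log2(FPKM + 1) of the deposited FPKM values, no low-count filter and a stricter one of 1 CPM in 3 libraries, the replicate number as a block, a log2 fold change of at least 1, the fit of only the groups compared, and each library left out in turn. After seeing the data, the libraries outlying in the principal components were left out together, and counts were fitted without normalization factors. Under each scaling the lists called by camera had more called members on the same side as with TMM, except carotenoid genes in the interaction, which had as many higher as lower without normalization factors.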

Results

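Transcript levels were measured by RNA sequencing in tomato fruit pericarp, the fleshy fruit wall, of a wild type (WT) and a mutant called cr. The labels do not name the mutated gene, and none was inferred. Fruit was sampled at mature green, labelled 35, and at breaker, labelled 38, the stage at which the first colour change shows, with 3 libraries in each of 4 groups. What 35 and 38 count is not stated. Total counts per library ran from 17703054 to 19426192, and 19664 genes had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical.

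The first principal component of log2 CPM (counts scaled to the library total) held 63.7% of the variance and followed stage. WT libraries scored between -61.21 and -39.94 at mature green and between 94.88 and 106.24 at breaker. The cr libraries scored between -78.67 and -65.16 at mature green and -4.25, 30.44 and 31.9 at breaker, so all 3 cr breaker libraries lay between the WT stages. Replicate 1 of cr at breaker held the lowest of the cr breaker scores, and WT mature green replicate 3 stood apart on the third component with a score of 40.63.

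**Figure D1:**
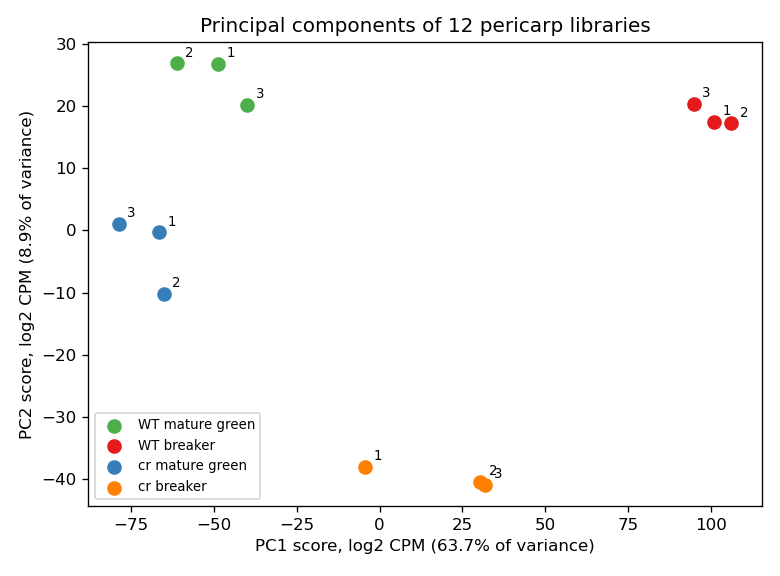
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, coloured by group, with the replicate number beside each point. On the horizontal axis the cr breaker libraries, from -4.25 to 31.9, lie between the WT mature green and WT breaker libraries.

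The change from mature green to breaker within WT shows what changed over this interval without the mutation. PG2A, the fruit polygalacturonase that degrades pectin, went from 35.2 ± 34.6 to 7987 ± 1360 CPM (SD, n = 3; log2 fold change 7.83 ± 0.89 (SE), adjusted p = 1.31e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). PL, a pectate lyase, rose from 122 ± 76.7 to 4000 ± 642 CPM, and PSY1, the phytoene synthase of fruit carotenoid formation, from 1003 ± 293 to 9797 ± 402 CPM (adjusted p = 2.78e-05 and 1.79e-06). The ethylene synthesis genes ACS2 and ACS4 rose from 10.4 ± 13.7 to 349 ± 63.2 and from 18.9 ± 13.1 to 151 ± 20.1 CPM (adjusted p = 0.00012 and 6.38e-05). The log2 fold change of PG2A was 9.03 without WT mature green replicate 3, that of ACS4 3.71 without the same library, and that of ACS2, 5.06 with all libraries, was 7.14 without WT mature green replicate 1.

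Among the 9 measured members of the cell wall softening list, 6 rose and 2 fell. With 6 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.0092, and adjusted p = 0.361 with an estimated correlation. Of 13 ripening regulators 8 rose and 1 fell, with NOR, a NAC factor, at 1.42, adjusted p = 0.00133, CNR at 1.74, adjusted p = 4.64e-05 and the MADS-box gene FUL1 at 2.04, adjusted p = 3.57e-07 (log2; 9 higher and 1 lower adjusted over the list alone). The test of that list gave camera adjusted p = 0.00503, and adjusted p = 0.415 with an estimated correlation. GLK2, a regulator of chloroplast development in fruit, was the member that fell (log2 fold change -4.71 ± 0.40 (SE), adjusted p = 1.11e-06). Of 20 carotenoid genes 13 rose and 5 fell, ZDS among the risers at 1.44, adjusted p = 3.57e-07. With 13 higher and 5 lower adjusted over the list alone, camera gave adjusted p = 0.00123, and adjusted p = 0.361 with an estimated correlation. Ethylene signalling genes rose in 10 of 17 cases and fell in 2. With 12 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.00819, and adjusted p = 0.522 with an estimated correlation. For ethylene synthesis 5 of 9 rose and 1 fell, but camera did not call the list. With 5 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 0.166. The list passed in fry, on the higher side (adjusted p = 0.023). ACO1, an ethylene-forming oxidase, rose (1.13, adjusted p = 0.016), and that call was lost without WT mature green replicate 2 (0.0679), or WT breaker replicate 1 (0.0665) (adjusted p in parentheses). ACO1 overlaps an opposite-strand feature of 2135 counts.

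All 3 chlorophyll breakdown genes rose, SGR1 at 1.45, adjusted p = 0.000279 (log2; 3 higher adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.427 with an estimated correlation). Aroma genes rose in 6 of 9 cases (6 higher adjusted over the list alone, camera adjusted p = 0.0054, and adjusted p = 0.361 with an estimated correlation), and flavonoid genes in 7 of 9, with 1 lower. With 7 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 0.00865, and adjusted p = 0.464 with an estimated correlation. Photosystem and antenna genes fell in 54 of 76 cases and rose in 8. With 8 higher and 56 lower adjusted over the list alone, camera gave adjusted p = 6.76e-08, and adjusted p = 0.463 with an estimated correlation. The chlorophyll a-b binding protein genes Solyc03g005760 and Solyc01g105030 fell by 4.77 and 2.73 on the log2 scale. Core histone genes fell in 32 of 53 cases and rose in 1. With 2 higher and 33 lower adjusted over the list alone, camera gave adjusted p = 6.83e-06, and adjusted p = 0.464 with an estimated correlation. Cytosolic ribosomal protein genes fell in 105 of 233 and rose in 2. With 2 higher and 105 lower adjusted over the list alone, camera gave adjusted p = 8.61e-07, and adjusted p = 0.691 with an estimated correlation. Without normalization factors 168 of them were lower. Heat shock genes went the other way, with 38 of 70 higher and 4 lower. With 40 higher and 5 lower adjusted over the list alone, camera gave adjusted p = 1.16e-06, and adjusted p = 0.415 with an estimated correlation. The small heat shock gene Solyc03g082420 rose from 19.8 ± 11 to 2100 ± 404 CPM. It overlaps a feature on the opposite strand that held 60 counts over the 12 libraries, and the strand setting is not given in the sources used here.

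Defence protein genes fell in 37 of 83 cases and rose in 13 (13 higher and 39 lower adjusted over the list alone, camera adjusted p = 0.00484, and adjusted p = 0.455 with an estimated correlation), among them the glucanase gene Solyc04g016470 at -3.18, adjusted p = 4.81e-08 (log2). Xylem and lignin genes fell in 18 of 36 and rose in 5. With 6 higher and 18 lower adjusted over the list alone, camera gave adjusted p = 0.0486, and adjusted p = 0.361 with an estimated correlation. That call was lost without WT mature green replicate 3 (0.063), WT breaker replicate 1 (0.0534), 2 (0.0594) or 3 (0.0692), cr mature green replicate 1 (0.0577), or cr breaker replicate 3 (0.0657). In it the cinnamoyl-CoA reductase gene Solyc06g068440 rose at 2.28, adjusted p = 4.7e-08, and the fasciclin-like gene Solyc01g091530 and the cinnamyl alcohol dehydrogenase gene Solyc03g078440 fell by 2.45 and 4.06. Pectin enzyme genes went both ways, 21 higher and 36 lower of 83. With 21 higher and 39 lower adjusted over the list alone, camera gave adjusted p = 0.0941. Pectate lyase Solyc06g083580, which overlaps an opposite-strand feature of 12 counts, fell (log2 fold change -3.45 ± 0.16 (SE), adjusted p = 2.63e-08). Pectinesterase Solyc06g009190 and pectin acetylesterase Solyc08g005800 fell by 4.93 and 3.01. GAME12 and GAME11, of steroidal glycoalkaloid synthesis, fell by 4.09 and 2.43 (adjusted p = 4.29e-08 and 2.06e-07), while the list of 7 had 5 lower and 2 higher. With 2 higher and 5 lower adjusted over the list alone, camera gave adjusted p = 0.107.

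Genes falling to near the detection limit included a dirigent protein gene, Solyc01g111230, from 23.9 ± 1.65 to 0.0992 ± 0.0688 CPM, and a receptor-like protein gene, Solyc01g086920, from 84.5 ± 30.3 to 0.158 ± 0.0322 CPM. Arginase gene Solyc01g091170 went from 47.9 ± 5.44 to 0.0995 ± 0.0357 CPM. The xyloglucan endotransglucosylase gene Solyc02g091920 had 762 counts over the mature green and 3 over the breaker libraries, a ratio of 226 (95% exact binomial interval 76.9 to 1100, counting error only). The log2 fold change of Solyc02g091920 was -7.66, or -8.51 without WT breaker replicate 2, and that of Solyc01g111230 -7.82, or -8.50 without WT breaker replicate 1. Another of that family, Solyc07g009380, fell by 3.39, proteinase inhibitor Solyc03g020060 by 6.20 and the late embryogenesis gene Solyc10g150145 by 3.30. In all, 4600 genes rose and 4898 fell (9498 of 19664), 4004 of them by at least 1 on the log2 scale. Upper quartile scaling moved the median over all genes to -0.10 and the higher share of calls from 48.4% to 37.5%, and counts without normalization factors, tried after seeing the data, gave 29.6%.

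The same stage change within cr asks how far the mutant fruit moved over the same interval. PG2A went from 4.03 ± 3.57 to 668 ± 421 CPM (log2 fold change 7.37 ± 0.90 (SE), adjusted p = 9.21e-05), PL from 29.1 ± 22.7 to 1596 ± 624 CPM and PSY1 from 669.5 ± 141 to 4969 ± 1710 CPM (adjusted p = 5.55e-05 and 2.38e-05). ACS2 and ACS4 rose by 7.54 and 4.68 on the log2 scale (adjusted p = 0.00015 and 3.14e-05), ACO1 by 1.71 (adjusted p = 0.00309), and E8, an ethylene-responsive oxygenase gene, from 332 ± 82.8 to 5869 ± 2130 CPM. The log2 fold change of PG2A was 8.31 without cr mature green replicate 1, and that of PL, 5.78 with all libraries, was 6.63 without cr mature green replicate 3.

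Ripening regulators rose in 10 of 13 cases and fell in 1 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.81e-05, and adjusted p = 0.361 with an estimated correlation), NOR at 2.33, adjusted p = 0.000134, CNR at 2.16, adjusted p = 4.21e-05 and GLK2 at -1.94, adjusted p = 0.000743 (log2). Softening genes rose in 7 of 9 and fell in 1 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000743, and adjusted p = 0.361 with an estimated correlation), with EXP1, an expansin, at 4.37, adjusted p = 1.38e-06. Ethylene synthesis genes rose in 6 of 9 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00451, and adjusted p = 0.409 with an estimated correlation) and ethylene signalling genes in 10 of 17, with 1 lower. With 10 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 0.000316, and adjusted p = 0.43 with an estimated correlation. Carotenoid genes rose in 9 of 20 and fell in 1 (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00259, and adjusted p = 0.361 with an estimated correlation), including GGPS2 at 3.77, adjusted p = 7.55e-06 and ZISO at 3.81, adjusted p = 3.44e-05. Aroma genes rose in 6 of 9 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000668, and adjusted p = 0.361 with an estimated correlation), AAT1, an alcohol acyltransferase, at 4.50, adjusted p = 3.24e-06 and LOXC, a lipoxygenase, from 11.1 to 177 CPM. AAT1 overlaps an opposite-strand feature that held 5764 counts over the 12 libraries. Flavonoid genes rose in 7 of 9. With 7 higher adjusted over the list alone, camera gave adjusted p = 0.00109, and adjusted p = 0.427 with an estimated correlation. All 3 chlorophyll breakdown genes rose (3 higher adjusted over the list alone, camera adjusted p = 0.00249, and adjusted p = 0.361 with an estimated correlation), SGR1 by 1.84.

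Photosystem and antenna genes fell in 45 of 76 cases and rose in 3 (4 higher and 52 lower adjusted over the list alone, camera adjusted p = 5.09e-10, and adjusted p = 0.427 with an estimated correlation), and cytosolic ribosomal protein genes fell in 44 of 233 and rose in 1. With 23 lower adjusted over the list alone, camera gave adjusted p = 7.59e-07, and adjusted p = 0.691 with an estimated correlation. The ribosomal protein genes called lower numbered 67 with upper quartile factors and 96 without factors. Chlorophyll synthesis genes fell in 7 of 16 and rose in 2. With 2 higher and 8 lower adjusted over the list alone, camera gave adjusted p = 0.0235, and adjusted p = 0.464 with an estimated correlation. Heat shock genes rose in 18 of 70 and fell in 3 (18 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0367, and adjusted p = 0.717 with an estimated correlation), a call lost without cr mature green replicate 2 (0.0705) or 3 (0.0603), or cr breaker replicate 3 (0.0519). Solyc03g082420 went from 29.2 ± 10.8 to 411 ± 75.3 CPM. Core histones had 4 higher and 2 lower of 53, but 2 higher and 2 lower without factors. With none adjusted over the list alone, camera gave adjusted p = 0.679. Other risers were pectate lyase Solyc09g091430 (6.31 log2), the pectinesterase inhibitor gene Solyc01g088590 (1.83), oleosin Solyc06g060840 (4.78, or 5.47 without cr mature green replicate 2), the auxin-related genes Solyc01g107390 (3.08) and Solyc09g008175 (5.64, or 6.52 without cr mature green replicate 1), WRKY gene Solyc02g021680 (4.11) and Solyc06g068440 (2.16). Those that fell included Solyc01g111230 (-4.98), Solyc01g086920 (-5.22), Solyc01g091170 (-4.83), Solyc02g091920 (-5.09), fasciclin-like Solyc07g053540 (-6.73), Solyc03g020060 (-3.35), aquaporin Solyc12g044330 (-2.33) and chitinase-like Solyc09g098540 (-1.36), which overlaps an opposite-strand feature of 11830 counts. Adjusted p for each gene of these groups was at most 3.44e-05.

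In all, 2997 genes rose and 2648 fell in cr (5645 of 19664), 1881 by at least 1 on the log2 scale. The count was 3691 without cr mature green replicate 3, and 37.5% of calls were higher without normalization factors against 53.1%. Of 4363 genes called in both genotypes, 4253 (97.5%) went the same way, 2220 up and 2033 down, where independent lists would share 701.1 and 659.6. These comparisons share no library.

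At mature green the comparison of cr with WT shows how the genotypes differed at the earlier labelled stage. EXP1, an expansin of fruit softening, stood at 47.7 ± 13.1 CPM in cr and 206 ± 62.1 in WT (SD, n = 3; log2 fold change -2.11 ± 0.24 (SE), adjusted p = 0.00055 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). E8 was at 332 ± 82.8 against 1433 ± 496 CPM and AAT1 at 94.7 ± 18.6 against 338 ± 121 CPM (adjusted p = 0.0033 and 0.00294). ACS4 was lower, too (log2 fold change -2.80, adjusted p = 0.00803), at -2.09 without WT mature green replicate 3.

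Of 9 softening genes 4 were lower (8 lower adjusted over the list alone, camera adjusted p = 4.36e-06, and adjusted p = 0.361 with an estimated correlation), including the mannanase MAN4a at -4.25, adjusted p = 0.00899 and the galactosidase TBG6 at -1.34, adjusted p = 0.00683 (log2). MAN4a was at -3.36 without WT mature green replicate 3 and at -5.36 without cr mature green replicate 1. TBG6 overlaps an opposite-strand feature of 3751 counts. PG2A was called at -3.13, adjusted p = 0.0426, but not without WT mature green replicate 3 (0.216), WT breaker replicate 1 (0.0588), 2 (0.0589) or 3 (0.0503), cr mature green replicate 2 (0.15) or 3 (0.129), or cr breaker replicate 2 (0.061). Without WT mature green replicate 3 its log2 fold change was -1.92, and without cr mature green replicate 1 it was -4.07. PG2A was not called either with both outlying libraries left out (0.0874), with only the mature green libraries (0.0611) or by limma on FPKM (0.0561). PL missed the threshold (-2.06, adjusted p = 0.0574) and passed it without WT mature green replicate 2 (0.0232), cr mature green replicate 3 (0.0253), or cr breaker replicate 1 (0.0444), by DESeq2 (0.0252) and with no low-count filter (0.0349). Its log2 fold change was -2.92 without cr mature green replicate 3.

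ACS2 was called at -4.09, adjusted p = 0.0458. It lost its call without WT mature green replicate 1 (0.177) or 3 (0.0604), WT breaker replicate 1 (0.0627), 2 (0.0634) or 3 (0.0566), cr mature green replicate 1 (0.13), 2 (0.12) or 3 (0.149), or cr breaker replicate 2 (0.064) or 3 (0.0551), with a log2 fold change of -2.02 without WT mature green replicate 1. It was not called either with only the mature green libraries (0.0661), without normalization factors (0.0511) or by limma on FPKM (0.16). The ethylene synthesis list had 2 lower of 9 (4 lower adjusted over the list alone, camera adjusted p = 0.0486, and adjusted p = 0.464 with an estimated correlation), and lost its call without WT mature green replicate 1 (0.0946), WT breaker replicate 2 (0.0545) or 3 (0.0542), cr mature green replicate 2 (0.0997), or cr breaker replicate 2 (0.063). Without normalization factors 1 of its members was lower. ACO1, NOR, CNR, PSY1, SGR1 and GLK2 were not called, at log2 fold changes of -0.70, -0.74, -0.57, -0.58, -0.67 and -0.47 and adjusted p of 0.286, 0.178, 0.188, 0.26, 0.136 and 0.408. Ethylene signalling genes had 1 lower and 0 higher of 17 (2 lower adjusted over the list alone, camera adjusted p = 0.0526), and that list passed without WT mature green replicate 2 (0.0277), cr mature green replicate 1 (0.000309), or cr breaker replicate 1 (0.0315). The ripening regulator list had 2 lower of 13. With 3 lower adjusted over the list alone, camera gave adjusted p = 0.00109, and adjusted p = 0.361 with an estimated correlation.

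Lower in cr were also 5 of 9 aroma genes (5 lower adjusted over the list alone, camera adjusted p = 0.000575, and adjusted p = 0.361 with an estimated correlation), 2 of 9 flavonoid genes (1 without normalization factors, 5 lower adjusted over the list alone, camera adjusted p = 0.00503, and adjusted p = 0.464 with an estimated correlation), 6 of 53 core histones (7 lower adjusted over the list alone, camera adjusted p = 7.59e-07, and adjusted p = 0.445 with an estimated correlation) and 2 of 7 glycoalkaloid genes (4 lower adjusted over the list alone, camera adjusted p = 0.00225, and adjusted p = 0.361 with an estimated correlation), GAME4 at -2.52, adjusted p = 0.000821. Seed storage and late embryogenesis genes had 5 lower and 1 higher of 77 (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.000329, and adjusted p = 0.361 with an estimated correlation), oleosin Solyc06g060840 at -3.08 and storage protein Solyc03g005580 at 3.10. These were at -3.77 without cr mature green replicate 2 and 3.89 without WT mature green replicate 3. Xylem and lignin genes had 4 lower of 36 (6 lower adjusted over the list alone, camera adjusted p = 0.0201, and adjusted p = 0.361 with an estimated correlation), fasciclin-like Solyc07g065540 at -1.28. Pectin enzymes had 8 lower and 2 higher of 83 (3 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0157, and adjusted p = 0.361 with an estimated correlation), a call lost without cr mature green replicate 2 (0.0775). Among them were pectate lyase Solyc09g091430 at -3.38, pectinesterase Solyc11g070175 at 0.53 and pectate lyase Solyc02g031960 at 2.17, the last not called without WT mature green replicate 3 (0.0641) or both outlying libraries (0.0556). Proteinase inhibitors had 2 lower of 30 (3 lower adjusted over the list alone, camera adjusted p = 0.0486, and adjusted p = 0.539 with an estimated correlation), Solyc08g080630 at -2.17 (-1.58 without WT mature green replicate 1) overlapping an opposite-strand feature of 24440 counts. That list was not called without WT mature green replicate 2 (0.0659), or cr mature green replicate 1 (0.122) or 2 (0.118).

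Photosystem and antenna genes were higher in 5 of 76 cases (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.88e-09, and adjusted p = 0.445 with an estimated correlation), such as the NDH subunit gene Solyc05g007780 at 1.26, adjusted p = 0.0103, which overlaps an opposite-strand feature of 644 counts. Chlorophyll synthesis genes were higher in 2 of 16 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.15e-05, and adjusted p = 0.361 with an estimated correlation), and heat shock genes in 2 of 70, with 1 lower. With 8 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 0.000329, and adjusted p = 0.464 with an estimated correlation. Carotenoid genes had 2 lower and 1 higher of 20 (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.931), GGPS2 at -1.77, adjusted p = 0.00894. Defence genes had 3 higher and 3 lower of 83 (3 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0941), and the list passed without WT mature green replicate 3 (0.0419), or cr mature green replicate 3 (0.0136). The pathogenesis-related genes Solyc02g031940 and Solyc02g031950 were higher at 2.46 and 1.99, and glucanase Solyc04g016470 lower at -1.04. Aquaporin Solyc12g044330 was higher at 1.48 and cytochrome gene Solyc07g055460 at 2.30. A gene annotated as a BED zinc finger protein, Solyc12g150108 (chromosome 12, 38102907 to 38104858 on SL4.0), had no count in the WT libraries and 32.3 ± 1.21 CPM in cr, at least 611-fold higher against a floor of 3 counts over the group. Solyc09g074380, a DCD domain gene (chromosome 9, 62384142 to 62386999), was at 2.24 ± 0.408 CPM in cr and 44.1 ± 2.56 in WT (log2 fold change -4.29 ± 0.18 (SE), adjusted p = 4.14e-08).

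In all, 338 genes were higher and 515 lower in cr (853 of 19664), 323 by at least 1 on the log2 scale. Without 1 library this count ran from 243 to 1183, the latter without cr breaker replicate 1. It was 243 without WT mature green replicate 3, 512 without replicate 1, and 373, 331 and 406 without cr mature green replicates 1, 2 and 3. With both outlying libraries left out, chosen after seeing the data, it was 472, and DESeq2's Wald test called 1424.

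At breaker the comparison of cr with WT shows how the genotypes differed at the later labelled stage. PG2A reached 668 ± 421 CPM in cr against 7987 ± 1360 in WT (log2 fold change -3.58 ± 0.73 (SE), adjusted p = 0.00327), and PSY1 4969 ± 1710 against 9797 ± 402 CPM (-0.98, adjusted p = 0.0184), a call lost without cr breaker replicate 1 (0.0555), where its log2 fold change was -0.72, and without both outlying libraries (0.0575). The chlorophyll a-b binding genes Solyc01g105030 and Solyc01g105050 and the photosystem I gene Solyc06g074200 were higher in cr (2.02, adjusted p = 1.65e-05, 2.19, adjusted p = 3.25e-05 and 1.98, adjusted p = 8.81e-06 on the log2 scale). GLK2 was higher, at 2.37 ± 0.615 against 0.475 ± 0.172 CPM (adjusted p = 0.00179). Its log2 fold change was 2.30, or 1.10 by limma on FPKM.

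Of 76 photosystem and antenna genes 42 were higher and 3 lower. With 46 higher and 4 lower adjusted over the list alone, camera gave adjusted p = 5.09e-10, and adjusted p = 0.427 with an estimated correlation. Core histones were higher in 22 of 53 cases (25 higher adjusted over the list alone, camera adjusted p = 4.47e-06, and adjusted p = 0.464 with an estimated correlation) and defence genes in 26 of 83, with 2 lower (28 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00109, and adjusted p = 0.415 with an estimated correlation), Solyc04g016470 at 2.18, adjusted p = 5.31e-06. Heat shock genes were lower in 27 of 70 and higher in 2 (6 higher and 29 lower adjusted over the list alone, camera adjusted p = 6.83e-06, and adjusted p = 0.43 with an estimated correlation), Solyc05g010670 at -0.98, adjusted p = 6.46e-05. Carotenoid genes were lower in 9 of 20 and higher in 2 (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0192, and adjusted p = 0.361 with an estimated correlation), CRTR-B2 at -1.48, adjusted p = 6.33e-05 and ZDS at -0.88, adjusted p = 7.31e-05. Softening genes were lower in 4 of 9 and higher in 1. With 1 higher and 5 lower adjusted over the list alone, camera gave adjusted p = 0.0069, and adjusted p = 0.361 with an estimated correlation. Aroma genes were lower in 5 of 9. With 5 lower adjusted over the list alone, camera gave adjusted p = 0.00503, and adjusted p = 0.361 with an estimated correlation. Flavonoid genes were lower in 3 of 9 and higher in 1 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0361, and adjusted p = 0.542 with an estimated correlation), lost without WT breaker replicate 1 (0.0534) or 3 (0.105), or cr breaker replicate 2 (0.102). Ribosomal protein genes had 19 higher and 2 lower of 233 (11 higher adjusted over the list alone, camera adjusted p = 0.0198, and adjusted p = 0.887 with an estimated correlation), not called without cr breaker replicate 1 (0.126) and of the opposite direction without WT breaker replicate 3 (0.481). Without normalization factors 53 of them were higher.

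Ripening regulators had 2 higher and 2 lower of 13. With 2 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.491. NOR, CNR, SGR1 and ACO1 were not called (log2 0.17, -0.16, -0.28 and -0.12, adjusted p = 0.714, 0.65, 0.424 and 0.835). The direction of ACO1 turned without WT breaker replicate 1 (0.09) or cr breaker replicate 1 (0.21) and with no factors (0.01), and that of CNR without cr breaker replicate 1 (0.05). ACS2 (-1.61, adjusted p = 0.0831) and PL (-1.33, adjusted p = 0.0908) missed the threshold with 12 libraries. ACS2 passed it without WT mature green replicate 1 (0.00643) or 2 (0.0401), and PL without WT mature green replicate 2 (0.0489), or cr mature green replicate 3 (0.0474). With only the 6 breaker libraries both passed (0.0122 and 0.015). ACS4 was called (-1.12, adjusted p = 0.0484), but not by DESeq2 (0.0913), with upper quartile factors (0.056), with no factors (0.0631), or without WT mature green replicate 1 (0.0552), WT breaker replicate 1 (0.097), 2 (0.0756) or 3 (0.109), cr mature green replicate 1 (0.0563), 2 (0.0627) or 3 (0.0514), or cr breaker replicate 1 (0.163) or 2 (0.0977).

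Glycoalkaloid genes GAME12 and GAME11 were higher at 2.37, adjusted p = 1.1e-05 and 1.65, adjusted p = 2.16e-05, in a list with 4 higher and 2 lower of 7. With 4 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.0846. From the xylem and lignin list, Solyc03g078440, Solyc11g072510 (described as a Rossmann-fold protein) and Solyc07g065540 were higher at 2.61, 1.80 and 2.49, with 14 of 36 members higher and 4 lower (15 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0871), a list that passed without cr breaker replicate 2 (0.0316). Among pectin enzymes 24 were higher and 11 lower of 83 (24 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.175), pectate lyase Solyc06g083580 and pectinesterase Solyc12g098340 at 2.13 and 1.25 and pectin lyase-like Solyc08g082170 at -1.80. Xyloglucan gene Solyc07g009380 stood at 151 ± 32.8 CPM in cr and 12.5 ± 2.55 in WT. Lipase gene Solyc10g079410 was higher at 4.60, and ethylene response factor Solyc04g009450, methylesterase Solyc02g065260 and ATPase gene Solyc06g071580 lower at -2.19, -5.02 and -4.23. Solyc10g079410 was at 5.29 without WT breaker replicate 2 but at 1.245 by limma on FPKM, and Solyc02g065260 was at -5.65 without cr breaker replicate 2. Solyc09g074380 was lower again at -3.96, and Solyc12g150108 again had no count in WT and 29.2 ± 5.08 CPM in cr, at least 491-fold higher.

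In all, 2760 genes were higher and 2165 lower in cr at breaker (4925 of 19664), 1899 by at least 1 on the log2 scale. With upper quartile scaling 64.3% of calls were higher against 56% with TMM, and 74.9% without normalization factors. Genes called for genotype at both stages numbered 439, of which 159 were higher and 170 lower at both, where independent lists would share 47.4 and 56.7.

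**Figure D2:**
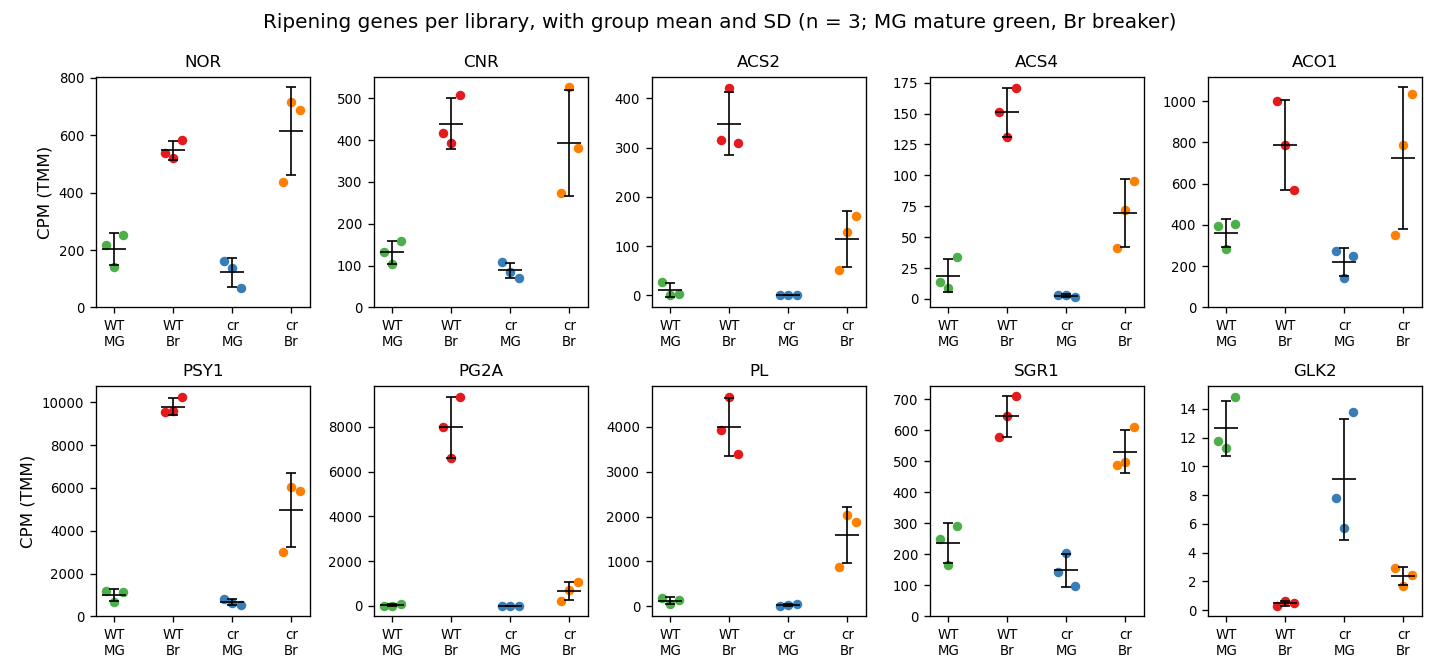
CPM of ripening genes fixed before the data were examined, each panel with its own linear axis, in 3 libraries (points) of each of 4 groups, with the group mean (dash) and SD (bar). PG2A reaches 7987 CPM in WT at breaker and 668 in cr, while NOR reaches 547 and 614.

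The interaction tests whether the stage change differed between cr and WT. Positive (higher) values mean a more positive change in cr. Glucanase Solyc04g016470 went from 89.3 ± 13.9 to 9.87 ± 1.37 CPM in WT and from 43.6 ± 8.88 to 44.8 ± 4.07 in cr (log2 difference 3.216, adjusted p = 1.2e-05). Heat shock gene Solyc05g010670 went from 184 ± 15.7 to 555 ± 54.8 CPM in WT and from 259.7 ± 13.4 to 281 ± 29.9 in cr (log2 fold change -1.48 ± 0.16 (SE), adjusted p = 0.000168). GLK2 differed at 2.77, adjusted p = 0.00445 (log2), and at 1.59 by limma on FPKM.

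Core histones were positive in 20 of 53 cases (24 higher adjusted over the list alone, camera adjusted p = 5.09e-10, and adjusted p = 0.361 with an estimated correlation), the H3 genes Solyc01g079110 and Solyc01g086820 at 1.81 and 1.74 and the H4 gene Solyc11g072860 at 1.60. Heat shock genes were negative in 23 of 70 and positive in 1 (2 higher and 31 lower adjusted over the list alone, camera adjusted p = 4.09e-09, and adjusted p = 0.361 with an estimated correlation), Solyc07g047790 at -1.44 and Solyc03g117630 at -1.93. Defence genes were positive in 16 of 83 and negative in 1 (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000132, and adjusted p = 0.361 with an estimated correlation), Solyc08g080650 at 2.82. Photosystem and antenna genes were positive in 16 of 76 and negative in 1 (26 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00123, and adjusted p = 0.68 with an estimated correlation), Solyc01g105030 at 1.91 and Solyc03g005760 at 3.08. Glycoalkaloid genes were positive in 5 of 7 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00168, and adjusted p = 0.361 with an estimated correlation), xylem and lignin genes in 9 of 36 (10 higher adjusted over the list alone, camera adjusted p = 0.00176, and adjusted p = 0.361 with an estimated correlation) and pectin enzymes in 24 of 83, with 4 negative. With 27 higher and 5 lower adjusted over the list alone, camera gave adjusted p = 0.00488, and adjusted p = 0.361 with an estimated correlation.

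Carotenoid genes were negative in 5 of 20 and positive in 1 (5 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0403, and adjusted p = 0.415 with an estimated correlation), a call lost without WT mature green replicate 2 (0.0661), WT breaker replicate 3 (0.0529), cr mature green replicate 2 (0.0705), or cr breaker replicate 1 (0.0561). Carotenoid members had 1 higher and 3 lower with upper quartile factors and 3 higher and 3 lower without factors, where neither side had the majority. Seed storage and late embryogenesis genes were positive in 17 of 77 and negative in 4. With 22 higher and 6 lower adjusted over the list alone, camera gave adjusted p = 0.0326, and adjusted p = 0.493 with an estimated correlation. That call was lost without WT mature green replicate 3 (0.0934), WT breaker replicate 1 (0.159), 2 (0.0882) or 3 (0.0531), cr mature green replicate 1 (0.0652), 2 (0.0857) or 3 (0.0779), or cr breaker replicate 1 (0.137) or 3 (0.0657). ACS2, ACO1, PSY1, PG2A, PL, NOR, CNR and SGR1 were not called (adjusted p = 0.237, 0.482, 0.552, 0.822, 0.584, 0.166, 0.444 and 0.492, with log2 differences of 2.48, 0.58, -0.40, -0.46, 0.74, 0.91, 0.41 and 0.39). PG2A was at -1.66 without WT mature green replicate 3 and turned direction, to 0.49 without cr mature green replicate 1. ACS2 was at 0.41 without WT mature green replicate 1 and at -0.06 by limma on FPKM, and PL was at 1.59 without cr mature green replicate 3. ACS4 was not called either (1.68, adjusted p = 0.0916; 0.97 without WT mature green replicate 3), but was without WT mature green replicate 2 (0.0379). In all, 1677 genes were positive and 908 negative (2585 of 19664), 1338 by at least 1 on the log2 scale. With upper quartile scaling 73.3% were positive against 64.9%, and 78.7% without normalization factors.

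**Figure D3:**
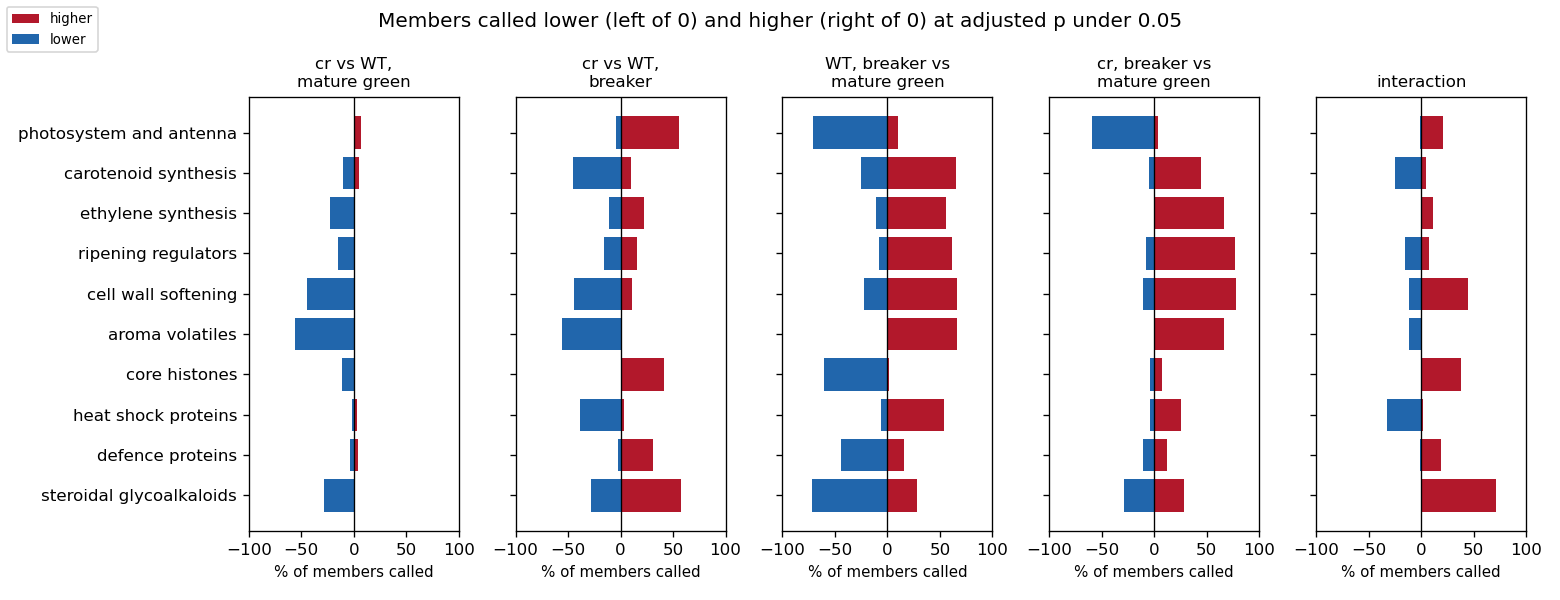
Percent of measured members of gene lists called higher (red, right of 0) and lower (blue, left of 0), a panel for each comparison. Photosystem and antenna genes have 54 of 76 members lower at breaker in WT, and 42 higher in cr than in WT at breaker.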

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

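The tests of other splits of the libraries, of single libraries for the smaller stage change and for the heat shock list, of neighbouring genes and of growing conditions were chosen only after the result was seen. Each result here differed between WT and cr in its change from mature green to breaker, by the interaction test. Genes called numbered 2585. The lists had camera adjusted p of 5.09e-10 for core histones, 4.09e-09 for heat shock proteins, 0.000132 for defence proteins, 0.00123 for photosystem and antenna genes, 0.00168 for steroidal glycoalkaloid genes, 0.00176 for xylem and lignin genes, 0.00488 for pectin enzymes, 0.0326 for seed storage and late embryogenesis genes and 0.0403 for carotenoid genes. With an estimated correlation the lowest adjusted p of these lists was 0.361.

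Differences in log2 change, cr minus WT, were 2.77 for GLK2, 2.28 for GAME11, 2.43 for GAME12 and 3.216 for the glucanase gene Solyc04g016470. They were 1.81, 1.74 and 1.60 for histone genes Solyc01g079110, Solyc01g086820 and Solyc11g072860, and 1.91 and 3.08 for chlorophyll a-b binding genes Solyc01g105030 and Solyc03g005760. Cell wall genes had 4.12 (xyloglucan endotransglucosylase Solyc07g009380), 2.79 (pectate lyase Solyc06g083580), -1.84 (pectin lyase-like Solyc08g082170), 3.77 and 2.28 (fasciclin-like Solyc07g065540 and Solyc07g048090). Heat shock genes Solyc05g010670, Solyc07g047790 and Solyc03g117630 had -1.48, -1.44 and -1.93. The rest were 1.88 for late embryogenesis gene Solyc10g150145, 5.09 for esterase Solyc03g121180 (6.39 without WT breaker replicate 3), 2.82 for pathogenesis-related Solyc08g080650, -2.55 for ethylene response factor Solyc04g009450, 0.88 for NAC gene Solyc11g008010 and -0.96 for auxin response factor Solyc05g047460. GLK2 was called with edgeR's quasi-likelihood test at adjusted p = 0.00445, and the other genes at adjusted p of at most 0.000677.

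For the counts of called genes, other splits of the 6 libraries of each 2-group comparison are too few for a share under 0.05: 1 of 10 splits, the real one, gave as many in each. The real counts were 853, 4925, 9498 and 5645, and the highest of other splits 1, 0, 0 and 1. For the interaction, 2 of 100 splits drawn from 200 gave as many as the real 2585. The other was the split with genotype labels exchanged at breaker alone, which sums the genotype differences (3855 genes), a structure of the samples. The highest of the rest was 2430. Splits that leave the genotype labels right at 1 stage carry the genotype difference of that stage, so these splits are no baseline without effects, and chance is not excluded by them.

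Over the 9498 genes called in WT, the slope of the cr change on the WT change was 0.488, and 0.558 without replicate 1 of cr at breaker, the highest without 1 library, which argues against a single library as the whole cause. Another scaling shifts all genes alike and hardly moves a slope (at most 0.489), so that test decides nothing. The reverse slope, over the 5645 genes called in cr, was 1.026 (0.936 to 1.061 without 1 library). Under selection of genes on the WT change it was predicted to be 1 or less, which this range does not decide. Selection alone, with changes of equal size in both genotypes, would lower both slopes about alike. The slope on the WT change was 0.445 to 0.558 without 1 library, below every reverse slope, which argues against selection as the whole cause over these genes. The signed mean log2 change was larger in cr for several ripening lists. It was 1.02 in WT and 2.30 in cr for ethylene synthesis, 0.595 and 1.004 for ripening regulators, 2.57 and 3.10 for softening and 1.70 and 2.20 for flavonoid genes. A smaller fall in cr, as of the regulator GLK2 (-4.71 in WT and -1.94 in cr), raises such a mean too. Of these 4 lists, softening (3.24 in WT and 3.02 in cr) and flavonoid genes (1.78 and 1.54) had the smaller median in cr. None of these 4 lists passed in the interaction (camera adjusted p = 0.0841, 0.436, 0.564 and 0.931), though ethylene synthesis did without WT breaker replicate 1 (0.024), or cr breaker replicate 1 (0.0228) or 2 (0.0404). Carotenoid (0.745 in WT and 0.603 in cr), photosystem and antenna (-1.676 and -0.796) and heat shock genes (1.034 and 0.321) had the smaller mean change in cr. Camera called each of these lists in the interaction, but only with the preset correlation. In fry the carotenoid (adjusted p = 0.0243) and heat shock genes (0.0127) passed there and the photosystem genes (0.147) did not. Ethylene signalling (1.052 and 1.034) and chlorophyll breakdown (1.306 and 1.29) hardly differed. Of genes called in both genotypes 97.5% went the same way. That share covers direction only and could be as high with changes of equal size, so it cannot decide how far cr went. That cr follows the WT course less far in part of the genes stays a hypothesis. The other lists called in the interaction also had a smaller mean change in cr. Means in WT and cr were -0.816 and 0.008 for core histones, -0.845 and 0.089 for defence and -1.279 and 0.331 for glycoalkaloid genes. They were -0.959 and -0.007 for xylem and lignin, -0.482 and 0.059 for pectin enzyme and -0.853 and 0.208 for seed and late embryogenesis genes. Each passed in fry (adjusted p at most 0.0308). Their camera calls needed the preset correlation, so the lists do not decide this hypothesis. A later harvest stage of WT fruit stays open, untested.

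Of 439 genes called for genotype at both stages, 329 (74.9%) went the same way and 110 opposite ways. The 329 were 3.16 times as many as independent lists would share. Without any 1 library the ratio was at least 3.1, which argues against a single library as the source. Among the 329 genes in the same direction at both, 24 pairs were next to each other on a chromosome, against a median of 5 and a highest of 17 in 10000 random sets (permutation p = 1e-04, the smallest these can give). A candidate explanation is a linked segment or another difference between the lines. Tandem copies, neighbours expressed together or reads shared between neighbours would give such pairs too and were not tested, and the mutation itself stays open.

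Heat shock genes rose in 38 of 70 cases in WT and 18 in cr, with 23 of 70 members lower in the interaction and a median of -0.49 on the log2 scale. The list call in the interaction is lost with an estimated correlation (adjusted p = 0.361). With the preset correlation its highest adjusted p without 1 library was 7.22e-08, which argues against a single library. Split by description, a split made after seeing the data, 19 of 34 members of the small class and 16 of 22 of the 70 kDa class rose in WT, and 12 and 10 were lower in the interaction, against 2 of 7 of the 90 kDa class and 1 of 7 others that rose, and 1 and 0 that were lower. Growing or harvest conditions that differed between the groups cannot be told apart from genotype and stage, since the labels give no other condition, and a biological difference stays open.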

How the results depend on the processing

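Leaving out the outlying libraries together and fitting without normalization factors were chosen only after the data were seen. In the order cr against WT at mature green, at breaker, stage in WT, stage in cr and interaction, the calls were 853, 4925, 9498, 5645, 2585, and with a log2 fold change of at least 1 in addition 323, 1899, 4004, 1881, 1338, by construction fewer. Without 1 library they ran from 243 to 1183, 3543 to 4979, 8087 to 9844, 3691 to 6041 and 1828 to 2657. At mature green DESeq2's Wald test called 1424 genes, and the fit without the outlying libraries 472. The Wald test started from 25536 genes, but edgeR with no low-count filter started from as many and called 873. That argues against the number of genes as the reason for the 1424, and other causes were not tested. The other alternatives stayed within 1.5 times of each count, and no called gene shared with an alternative changed sign in any. The ribosomal protein list at breaker had adjusted p from 3.95e-06 to 0.481 without 1 library, the latter without WT breaker replicate 3 and in the opposite direction, and the cause was not tested. The replicate number as a block gave 603, 4358, 8978, 4941, 2044 calls, but same-numbered libraries did not deviate together (r from -0.152 to 0.08), so the numbers do not pair them. With the block PG2A and ACS2 at mature green (0.0974 and 0.0927) and the xylem and lignin list over ripening in WT (0.0539) were not called, and the cuticle list at mature green was (0.0493). The cuticle list had camera adjusted p = 0.0849 with all libraries and no member called. It passed also without WT mature green replicate 3 (0.00292) or cr mature green replicate 3 (0.00446). Of the rule's 527 named values, 436 were called and 301 of these kept their side under every alternative run. The alternative that asks for a log2 fold change of at least 1 drops smaller called changes by construction. Of the 91 not called, 76 passed under none. In the order above, 22 of 60, 57 of 90, 95 of 108, 76 of 99, 51 of 79 called values were kept. Depth limits low genes: a floor of 3 counts over a group was 0.0529 to 0.0595 CPM. Limma on log2(FPKM + 1) kept the side of 158 of the 160 values in the text, but gave smaller changes for several. At mature green GAME4 went from -2.52 to -1.36 and Solyc09g091430 from -3.38 to -1.74. Over ripening in WT Solyc02g091920 went from -7.66 to -3.31.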

Other observations

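The heat shock classes and the neighbouring pairs given above were examined only after the data were seen. Regulator families went both ways over ripening. Ethylene response factors had 16 higher and 30 lower of 79 (16 higher and 30 lower adjusted over the list alone, camera adjusted p = 0.246) in WT and 13 higher and 19 lower of 79 (13 higher and 22 lower adjusted over the list alone, camera adjusted p = 0.195) in cr, where the list passed without cr mature green replicate 2 (0.0409). NAC factors had 11 higher and 7 lower of 47 (10 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.56) in WT, but 8 higher and 10 lower with upper quartile factors, and WRKY factors 13 higher and 11 lower of 45 (13 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.491), but 11 higher and 12 lower without factors. MADS-box factors had 9 higher and 5 lower of 37 (8 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.694) in WT, but 7 higher and 8 lower with upper quartile factors and 6 higher and 9 lower without factors. In cr they had 8 higher and 3 lower of 37 (8 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0459, and adjusted p = 0.361 with an estimated correlation), or 4 higher and 3 lower without factors. That call was lost without WT mature green replicate 1 (0.0552), 2 (0.0581) or 3 (0.0661), WT breaker replicate 1 (0.0622), 2 (0.0618) or 3 (0.07), cr mature green replicate 1 (0.083) or 3 (0.0671), or cr breaker replicate 1 (0.0749) or 2 (0.0541).

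Aquaporin genes had 4 higher and 15 lower of 33 (4 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.0661) in WT and 3 higher and 9 lower of 33 (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0712) in cr. They passed in WT without WT mature green replicate 3 (0.0434), or WT breaker replicate 2 (0.0347) and in cr without cr breaker replicate 1 (0.0175). Expansin and xyloglucan endotransglucosylase genes had 8 higher and 13 lower of 38 (9 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.385) in WT. Auxin-responsive genes had 15 higher and 22 lower of 71 (15 higher and 22 lower adjusted over the list alone, camera adjusted p = 0.928) in WT, with a median of 0.09 and a mean of -0.04 on the log2 scale. Sugar, starch and acid genes had 1 higher and 4 lower of 6 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.137) and cuticle genes 1 higher and 3 lower of 5. With 1 higher and 3 lower adjusted over the list alone, camera gave adjusted p = 0.828. In cr the cuticle list had a median of -2.68 although camera placed it on the higher side (camera adjusted p = 0.854). At mature green the auxin-responsive list had a median of 0.01 and a mean of -0.17, and the expansin list 0.16 and -0.09. Median and mean differed in sign also for ethylene synthesis at breaker (-0.12 and 0.16) and pectin enzymes over ripening in cr (-0.14 and 0.06).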
